A study of Hydra viridissima with 2 samples.

How the data were processed

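Transcription start sites were mapped by CAGE, a method that captures the capped 5′ end of RNA, in whole green hydra (Hydra viridissima) of clone 2. One library came from aposymbiotic animals, which lack the green algal symbiont, and 1 from symbiotic (green) animals, so each group had 1 library and no comparison had a replicate check. Per the labels' protocols, each RNA pool came from about 200 large polyps kept at 24 °C, fed brine shrimp and collected after days without food, and the RNA integrity number was 10 in both. The protocol removed caps enzymatically, ligated a biotinylated dinucleotide to the freed 5′ ends, primed reverse transcription at random and captured the products on streptavidin beads. Reads carrying the ligated dinucleotide mark capped ends, per the labels' protocols.

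The submitters' processing notes name fastp 1.1.0 and STAR 2.7.11b, without settings. The genome build, the annotation, the tag counter and any removal of duplicate reads are not given in the sources used here. For each library the authors deposited raw counts of 5′ tags at single bases on each strand, with no normalization, and raw tag counts summed over start site clusters. The rule behind the clusters was worked out from the files: joining positions separated by at most 20 bases without regard to strand, and keeping totals of at least 5 tags, rebuilt 100% of the 63085 deposited clusters with their tag counts. When strands were kept apart, 62753 were rebuilt. The cluster lists give each cluster a single strand, and for a small number this is the strand with the fewer tags. Tags on the other strand of such a cluster enter the counts only where the other library lists the cluster on that strand. Giving each cluster the strand with most of its tags, an alternative chosen after the data were seen, left 1 cluster higher and 3 lower by the 4-fold rule, as in the comparison reported.

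Union clusters were built by merging overlapping or adjoining deposited clusters of either library on the listed strand, which gave 42241. Tags were then counted within each union cluster on that strand from the single-base counts and scaled by the total tags of the library to give CPM. A single tag was worth 0.468 CPM in the aposymbiotic and 0.255 CPM in the symbiotic library, and 3 tags, the limit that a count of 0 allows, were worth 1.40 and 0.764 CPM. Clusters with a mean of at least 10 CPM over both libraries were eligible for comparison, and the ratio was taken on the scale of CPM + 1, which understates the change of low clusters. With a single library per group no p-value was computed, and differences were counted by size: a ratio of at least 4, with 2 as an alternative. Folds printed for named clusters and loci are ratios of CPM without the added 1, unless the scale of CPM + 1 is stated. The 4-fold and 2-fold rules and the ranking use CPM + 1. Their 95% intervals are exact binomial intervals on the 2 tag counts, shares have exact Clopper-Pearson intervals, and tag counts have exact Poisson intervals. All of these cover counting error only, since amplified reads are not independent molecules.

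As a baseline for counting error, the tags of both libraries were pooled and split at random 20 times between libraries of the observed depths. To compare cluster numbers and shapes at equal depth, the symbiotic library was thinned at random to the aposymbiotic total (54.5% of its tags kept), with 20 draws for numbers of positions and clusters. Width was the distance from the 10th to the 90th percentile of the tags in clusters with at least 20 tags in each library, and sharp meant 10 bases or less. The dominant start site was the base with the most tags. Shifts within a cluster were measured by the Kolmogorov-Smirnov and the total variation distance between the tag profiles, in clusters with at least 50 tags in each library. Clusters on the same strand separated by at most 1000 bases were also summed into 14777 loci. This grouping was chosen after the data were seen and stands in for transcripts, since gene models were not used here.

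The regions named are the 8 eligible clusters with the largest ratio in each direction, the 5 clusters with the most tags in each library and the 3 with the largest shift, a rule set before the data were examined. They are given by scaffold, first and last base counted from 1, and strand. Planned work on initiator sequence, on location relative to genes and on gene lists needed a genome or gene models, which were not used here, so these parts were not run. Whether the tagged positions are true start sites was thus not checked, and start site here means the position of a 5′ tag. Alternatives covered the scaling (TMM factors from edgeR 4.0.16 in R 4.3.3, or the median ratio set to 1), the added constant, the filter on low clusters, the clusters used, capped positions and depth. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

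The counting rules were tested on simulated data. For the comparison of symbiotic with aposymbiotic, tags were drawn for the union clusters at the real depths with 200 clusters changed by known folds, 50 of each size. The changed clusters were picked among those with at least 10 CPM over the pooled tags. Their recovery therefore leaves out changes lost to the filter on low clusters. The 4-fold rule recovered 98% of the clusters changed 8-fold, 100% of those changed 16-fold and 2% of those changed 3-fold. Among 4009 unchanged eligible clusters it called 0, and the 2-fold rule called 5. The draws held Poisson counting error only, so these numbers leave out false calls from amplification or preparation. Of 100 simulated profiles with the use of 2 start sites exchanged, 98 passed the Kolmogorov-Smirnov distance of 0.5, against 0 of 100 without exchange. Each profile held only 2 single-base peaks, and the exchange was set larger than the cut. Passing was thus nearly fixed, and smaller shifts or broad profiles were not tested.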

Results

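CAGE tags were counted at single bases in 1 library from aposymbiotic and 1 from symbiotic green hydra. The aposymbiotic library held 2138180 tags at 376027 stranded positions, and the symbiotic library held 3926689 tags at 573257 positions, 1.84 times as many tags. Tags lay on the plus strand in 54.2% and 54.3% of cases. Positions with a single tag held 10.6% of the aposymbiotic and 8.56% of the symbiotic tags. The most used 100 positions held 12.4% and 13.4% of the tags. The 170867 positions seen in both libraries held 87.6% of the aposymbiotic and 84.9% of the symbiotic tags. Since there were no replicates, every difference below compares these libraries and not the conditions in general.

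The first comparison asked which start site clusters were used in each kind of animal. The cluster lists held 23776 clusters in the aposymbiotic and 39309 in the symbiotic library, with 89.8% (interval 89.7 to 89.8) and 92.4% (92.4 to 92.4) of all tags. At equal depth the direction turned for clusters but not for positions. The same clustering on single strands gave 23754 aposymbiotic clusters and 22865 ± 65.9 symbiotic clusters (SD over 20 thinning draws, which covers only the thinning). Positions numbered 376027 in the aposymbiotic and 393216 ± 371 in the thinned symbiotic library, with 10.6% and 12.0% of tags at positions with a single tag. The median deposited cluster was 20 bases wide with 8 tags in the aposymbiotic library and 21 bases wide with 9 tags in the symbiotic library. Use was concentrated in few clusters, with the 100 strongest holding 48.8% of aposymbiotic and 51.3% of symbiotic tags.

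Of the aposymbiotic clusters, 83.3% (82.8 to 83.8) overlapped a symbiotic cluster on the same strand, and 47.7% (47.2 to 48.2) of the symbiotic clusters overlapped an aposymbiotic one. With both lists called at equal depth these shares were 65.9% and 68.1%. Sharing followed the number of tags. Of clusters with 5 to 9 tags, 72.2% of the aposymbiotic and 23.1% of the symbiotic ones were shared, against 98.7% and 99.1% of those with at least 50 tags. When each cluster was given the strand that held most of its tags, 1 of 2062 aposymbiotic and 5 of 3352 symbiotic clusters with at least 50 tags were not shared. The largest unshared clusters then had 53 and 90 tags. At this depth, clusters with few tags could not be called present in a single kind of animal.

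The main comparison asked which clusters differed in level between symbiotic and aposymbiotic animals. The most used clusters were nearly the same in both. The strongest, on scaffold_5 from base 4513286 to 4513889 on the minus strand, had 21226 CPM in the aposymbiotic and 28810 CPM in the symbiotic library, 1.36-fold higher (1.34 to 1.37). The cluster on scaffold_7 from 7415296 to 7415535 on the plus strand had 20004 and 23085 CPM, 1.15-fold higher (1.14 to 1.17). The cluster on scaffold_7 from 9738216 to 9738565 on the minus strand had 13107 and 15128 CPM, also 1.15-fold higher (1.14 to 1.17). The cluster on scaffold_12 from 6809335 to 6809617 on the minus strand had 10437 and 11139 CPM. Its log2 ratio of 0.09 depends on the scaling for its direction, since with TMM factors the median log2 ratio of the eligible clusters fell by 0.11. The remaining clusters among the 5 strongest of either library were on scaffold_1 and scaffold_5. The former, from 32069580 to 32070072, plus strand, had 10406 CPM aposymbiotic and 8150 CPM symbiotic. The latter, from 9142017 to 9142150, plus strand, had 9243 CPM aposymbiotic and 11636 CPM symbiotic. Another strong cluster on scaffold_5, ending at base 4513126, is left out of these levels. Both lists give it the plus strand, so its 21948 aposymbiotic and 35827 symbiotic minus tags were not counted.

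Of 4179 eligible clusters, which held 81.5% of aposymbiotic and 81.8% of symbiotic tags, 1 was at least 4-fold higher and 3 were at least 4-fold lower in the symbiotic library. The higher one lay on scaffold_9 from 18042729 to 18042746 on the minus strand, with 2 aposymbiotic tags (0.242 to 7.22) and 90 symbiotic tags (72.4 to 111), a 24.5-fold difference in CPM (6.59 to 205). The lowest one lay on scaffold_6 from 7329385 to 7329436 on the minus strand, with 53 aposymbiotic tags (39.7 to 69.3) and 4 symbiotic tags (1.09 to 10.2), 24.3-fold lower (8.96 to 92.6). The others were on scaffold_4 from 2706090 to 2706125, plus strand, with 56 and 19 tags (5.41-fold lower, 3.17 to 9.65), and on scaffold_12 from 11256149 to 11256236, plus strand, with 59 and 22 tags (4.93-fold lower, 2.97 to 8.44). None of the 4 clusters reached a mean of 20 CPM, so with that filter 0 were left in either direction. The calls on scaffold_4 and scaffold_12 were also lost in other settings. On scaffold_4 the log2 ratio was -1.66 with 5 CPM added and -1.85 with the symbiotic library thinned, and on scaffold_12 it was -1.62 with 5 CPM added. Summed with their neighbours into loci, they had log2 ratios of -0.28 and -1.42. The 8 clusters with the largest ratios in favour of the symbiotic library ranged from 3.01-fold to 24.5-fold, or 2.73-fold to 12.4-fold on the scale of CPM + 1. They included a neighbouring pair on scaffold_16 from 1952170 to 1952230 (12 and 74 tags, 3.36-fold) and from 1952328 to 1952427 (17 and 94 tags, 3.01-fold). The 8 in favour of the aposymbiotic library ranged from 3.70-fold to 24.3-fold, or 3.57-fold to 12.8-fold on the scale of CPM + 1. Among these the cluster with the most tags lay on scaffold_1 from 34069545 to 34069647 on the minus strand, with 163 and 81 tags (3.70-fold lower, 2.81 to 4.89).

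**Figure D1:**
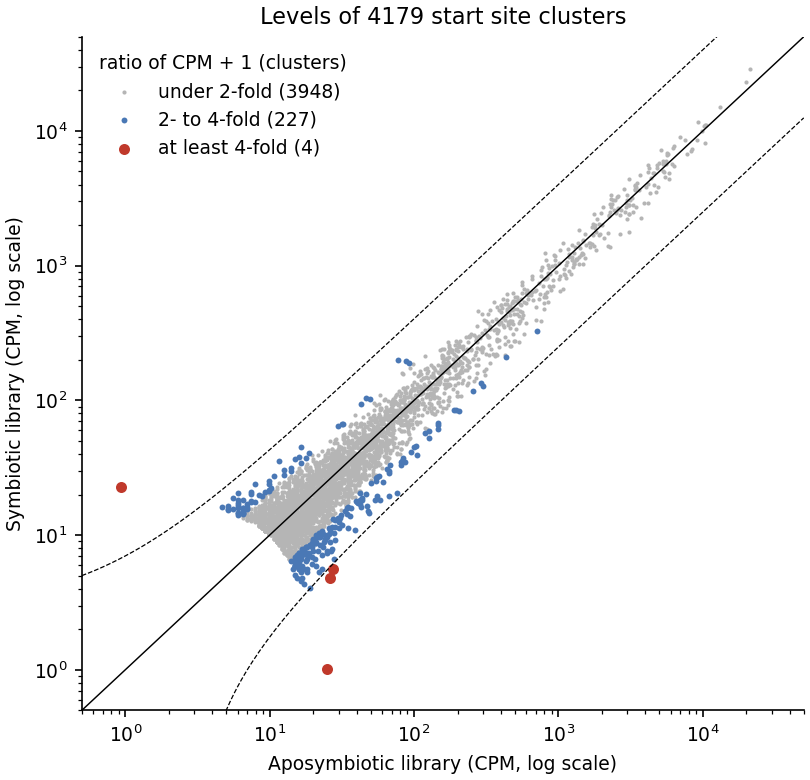
Level of each eligible cluster in the aposymbiotic (x) and symbiotic (y) library in CPM on log axes, 1 point per cluster. The solid line marks equal levels and the dashed lines a 4-fold ratio of CPM + 1, beyond which 4 of 4179 clusters lie.

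Most eligible clusters, 94.5%, were within 2-fold. Across these clusters, which are not replicates, the log2 levels correlated with a Pearson r of 0.964 and a Spearman rho of 0.861, and random splits of the same tags gave r from 0.990 to 0.991. Over all 42241 union clusters r was 0.827 and rho 0.587. The SD of the log2 ratios was 0.51, against 0.25 to 0.26 in the random splits. By the 2-fold rule 61 clusters were higher and 170 lower in the symbiotic library, and no random split gave more than 11 in both directions together, a baseline that treats each tag as an independent molecule. The lower clusters made up 73.6% (67.4 to 79.2, an interval that treats clusters as independent), and this share moved with the scaling and with the set of clusters or loci counted. It was 86.7% with TMM factors (38 higher, 248 lower). The direction of the excess turned in settings that treat the libraries unequally. With no filter the share was 32.4% (9051 higher, 4345 lower). There, 20571 symbiotic and 3967 aposymbiotic clusters, called at unequal depth, had no partner in the other list. With positions capped at the 99th percentile it was 36.6% (412 higher, 238 lower). The caps were 71 aposymbiotic and 80 symbiotic tags at 1.84 times the depth, so they cut the symbiotic library harder. Capping also changed the library totals and raised the number of eligible clusters to 7354. Neither turn can be told apart from these inequalities. By locus, with clusters on the same strand at most 1000 bases apart summed, 83 were higher and 90 lower, 52.0% (44.3 to 59.7). Loci holding an eligible cluster had 17 higher and 46 lower, 73.0% (61.5 to 83.3), and the others had 66 higher and 44 lower, 40% (30.9 to 49.5). With clusters called and counted at equal depth, 73 loci were higher and 121 lower, 62.4% (55.4 to 69.3), and those holding no eligible cluster were 55.2% lower (46.6 to 63.8). The intervals for these sets come from drawing blocks of neighbours.

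**Figure D2:**
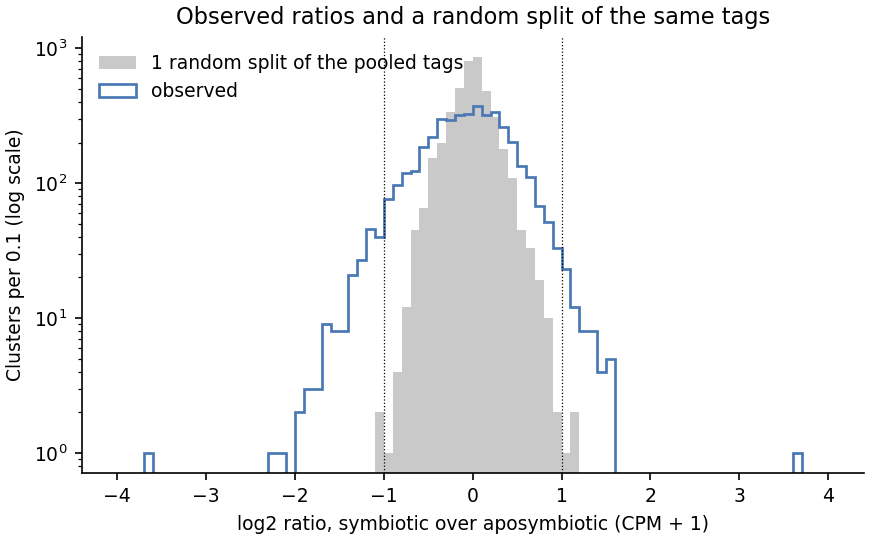
Number of clusters (y, log scale) by log2 ratio of CPM + 1, symbiotic over aposymbiotic (x), observed (line) and in 1 random split of the pooled tags (filled). Dotted lines mark 2-fold, and the observed ratios spread more widely, with an SD of 0.51.

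Neighbouring clusters differed together. Over 2078 pairs of adjacent eligible clusters on the same strand with at most 1000 bases between them, the log2 ratios correlated with r = 0.45, against -0.04 to 0.06 in the random splits. Over gaps above 1000 and up to 5000 bases r was 0.36 and rho 0.34 (286 pairs), and over gaps above 5000 and up to 20000 bases r was 0.29 and rho 0.16 (158 pairs), with no random splits computed for these distances. Over gaps above 20000 and up to 100000 bases r was -0.04. Summed into loci, of which those named here were chosen after their values were seen, 5 were at least 4-fold higher and 8 at least 4-fold lower in the symbiotic library, against 0 in every random split. The locus on scaffold_6 from 7329239 to 7330034 on the minus strand had 164 aposymbiotic and 23 symbiotic tags in 12 clusters, 13.1-fold lower (8.43 to 21.2). A neighbouring locus on the same strand, from 7317560 to 7318105, had 165 and 62 tags, 4.89-fold lower (3.63 to 6.66). The locus on scaffold_9 from 18042604 to 18043067 on the minus strand had 17 and 249 tags in 5 clusters, 7.98-fold higher (4.88 to 13.9). On scaffold_8 from 13842681 to 13843539, plus strand, a locus had 4 and 76 tags, 10.3-fold higher (3.88 to 38.9).

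**Figure D3:**
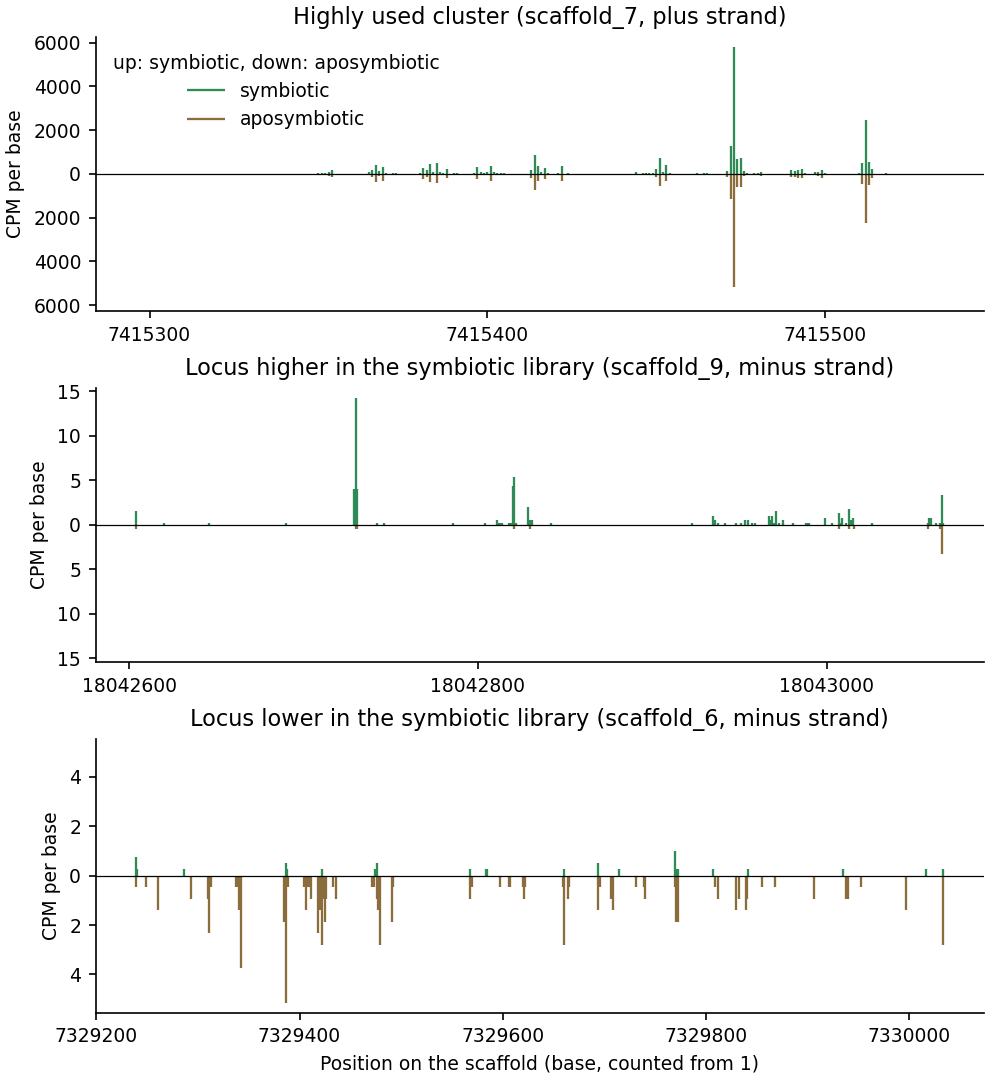
CPM at each base (y) along the scaffold (x) for a strongly used cluster and for the loci on scaffold_9 and scaffold_6, with the symbiotic library drawn upward and the aposymbiotic library downward. In the locus on scaffold_6, 164 aposymbiotic tags stand against 23 symbiotic tags.

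The ratio also changed with the position of a cluster along its locus. Across 3917 eligible clusters in loci of at least 3 clusters, the log2 ratio fell from the 5′ to the 3′ end with a Spearman rho of -0.17, against -0.03 to 0.04 in the random splits. With each locus divided into 5 equal segments, the median was 0.05 in the segment nearest the 5′ end and -0.24 in the segment nearest the 3′ end. In that last segment 7.25% of the clusters were at least 2-fold lower and 0.509% at least 2-fold higher in the symbiotic library, against 3.00% and 1.64% in the segment at the 5′ end. Of all tags in these loci, the segment nearest the 3′ end held 13.3% in the aposymbiotic and 11.5% in the symbiotic library.

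**Figure D4:**
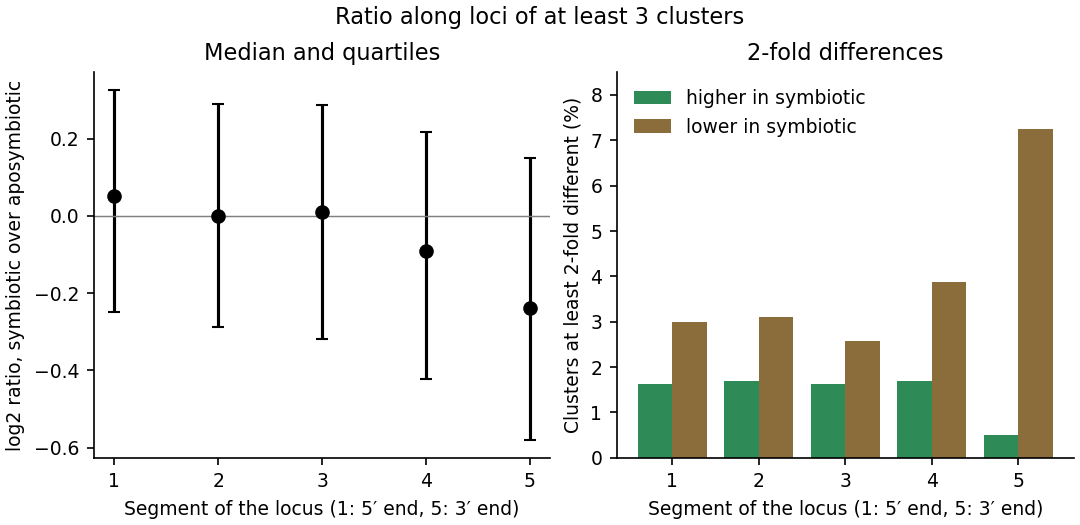
Clusters by segment of their locus from the 5′ end (1) to the 3′ end (5): median log2 ratio, symbiotic over aposymbiotic, with quartiles as bars (left), and the percent of clusters at least 2-fold higher or lower (right). The median falls to -0.24 and the share lower reaches 7.25% in the last segment.

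The shape of the clusters was compared at equal depth. In 3835 clusters the median width was 61 bases in the aposymbiotic and 62 bases in the symbiotic library, with sharp shares of 8.53% (7.66 to 9.46) and 8.42% (7.56 to 9.35), a difference within counting error. The median difference within a cluster was 0 bases. A width difference above 20 bases occurred in 16.3% of clusters, against 11.9% to 13.1% in random splits.

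**Figure D5:**
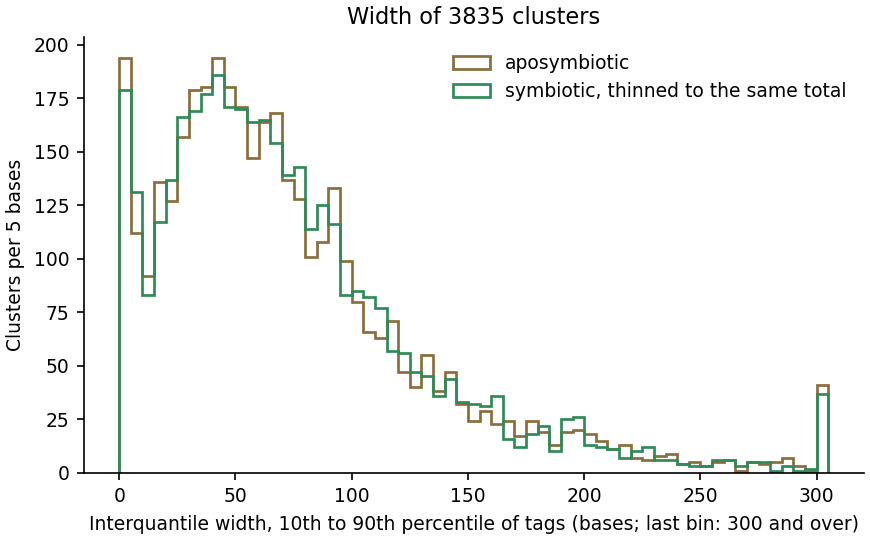
Number of clusters (y) by width from the 10th to the 90th percentile of tags in bases (x) for 3835 clusters in the aposymbiotic library and the symbiotic library thinned to the same total. The distributions have medians of 61 and 62 bases.

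The dominant start site was the same base in 61.9% (60.3 to 63.4) of these clusters, below the 66.5% to 68.0% of the random splits, and it was displaced by over 20 bases in 721, against 597 to 666. The share at the same base was 87.2% (83.3 to 90.6) in the 345 clusters with at least 500 tags in each library, against 89.9% to 92.2% in the splits. No cluster of 2009 had a Kolmogorov-Smirnov distance of at least 0.5, and the random splits gave 0 as well. A distance of at least 0.3 occurred in 9 clusters, against 0 to 2 in the splits, and the median distance was 0.0932, against 0.0695 to 0.0726. A total variation distance of at least 0.5 occurred in 67 clusters, against 11 to 20 in the splits. The largest Kolmogorov-Smirnov distance, 0.353, was below the highest of the splits, 0.373. That maximum was taken over all 2009 clusters and was not matched on tags, so it is no measure for clusters with more tags. The largest observed distance belonged to the cluster on scaffold_10 from 1941633 to 1941713, minus strand, with 53 and 55 tags. Its dominant base lay at 1941658 in the aposymbiotic and at 1941703 in the symbiotic library. On scaffold_8 from 6089529 to 6089604, minus strand, with 196 and 747 tags (distance 0.338), the dominant base was the same and the width was 62 bases in the aposymbiotic and 20 bases in the symbiotic library. On scaffold_11 from 10111581 to 10111634, minus strand, with 76 and 97 tags (distance also 0.338), the dominant base lay at 10111581 and at 10111632.

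Paired starts on opposite strands were rare, and most of the pairs counted by listed strand were lost when strands were set by the tags. Of the union clusters, 0.632% (0.559 to 0.712) had a cluster on the opposite strand with its dominant base 1 to 500 bases upstream, and 0.973% (0.882 to 1.07) had one at the same distance downstream. With each cluster on the strand of most of its tags the shares were 0.168% (0.132 to 0.212) and 0.287% (0.238 to 0.343), and clusters called anew with strands kept apart gave 0.173% and 0.362%. Among the 4179 eligible clusters 2 had an upstream partner and 0 had a downstream one (exact upper bound 0.0882%).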

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

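The tests of the listed strand were chosen after the result was seen. In the aposymbiotic library 1.28% of all tags, and in the symbiotic library 5.16%, lay inside a deposited cluster but on the strand opposite to the one listed for it, a signal outside the strand that each list gives.

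Most of these tags belong to a few strong clusters. On scaffold_5 from 4513286 to 4513890 the symbiotic cluster is listed on the plus strand with 113128 tags, of which 113127 are on the minus strand, and the aposymbiotic cluster over the same bases is listed on the minus strand. Joining positions without regard to strand rebuilt 100% of the deposited clusters, in line with a single stray plus tag setting the listed strand. Opposite strands being used in the 2 kinds of animal is argued against, since of 89 overlapping pairs listed on opposite strands 0% had most of their tags on opposite strands. The strongest cluster of both libraries would look specific to each by listed strand, although its tags are on the minus strand in both. Another strong cluster on scaffold_5, ending at base 4513126, is listed on the plus strand in both libraries. Of its 21949 aposymbiotic tags 21948 are on the minus strand, and of its 35829 symbiotic tags 35827 are. These minus tags are therefore missing from the main comparison.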

How the results depend on the processing

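Settings named majority strand, loci, clusters called at equal depth and locus segments, and every alternative for the 2-fold counts, were chosen after the data were seen. Of 121 values under alternatives, 81 moved by more than counting error or 1.5 times. The order of paired values did turn in places: the numbers of clusters and the shared percentages at equal depth, the 4-fold split with capped positions, the 2-fold split with no filter and with capped positions, and the sharp shares (25th to 75th percentile, 50 tags) and median widths (50 tags), which lay close together throughout. With 1 library per group none could be left out. No paired analysis was possible because each group has 1 library. The alternatives for initiator sequence, genomic location and gene lists were not run. Clusters with few tags are limited by depth: the number of clusters and the unshared share rest on them. Unless a reason is given, the cause was not tested.

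Minimums of 10 and 20 tags left 10479 and 4880 aposymbiotic and 18403 and 8629 symbiotic clusters, by construction, and equal depth left 22785 symbiotic clusters in a single thinning draw. The shared percentages (aposymbiotic, symbiotic) were 70.8 and 32.9 with 50% overlap, 66.6 and 40.3 by dominant positions, 91.1 and 49.1 from 10 tags, 95.1 and 51.0 from 20 tags, and 65.9 and 68.1 at equal depth. Pearson r was 0.764 with 0.5 CPM added, 0.935 with 5 CPM added and 0.964 at a mean of at least 10 CPM, where rho was 0.861.

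Clusters at least 4-fold different, main values 1 higher and 3 lower, were 5 lower with TMM factors, 5 lower with 0.5 CPM added, 1 lower with 5 CPM added, 13 higher and 15 lower from 5 CPM, 0 and 0 from 20 CPM, 238 and 259 with no filter, 18 and 13 with capped positions, 2 and 5 with the symbiotic library thinned, 5 and 8 by locus, and 61 and 170 at 2-fold. The 2-fold counts moved to 38 higher with TMM factors, 25 and 88 with 5 CPM added, 271 and 431 from 5 CPM, 20 and 67 from 20 CPM, 9051 and 4345 with no filter, 412 higher with capped positions and 83 higher and 90 lower by locus. Unshared clusters, 20571 symbiotic against 3967 aposymbiotic, enter without a filter.

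Percent sharp (aposymbiotic, symbiotic) was 22.0 and 22.2 from the 25th to the 75th percentile, 6.31 and 5.89 at 5 bases or less, 14.3 and 14.1 at 20 bases or less, 4.41 and 4.69 from 50 tags, and 10.6 and 9.79 without thinning. Median widths were 34 and 35, 86 and 85, and 55 and 57 bases for the percentiles, 50 tags and no thinning. The dominant base was the same in 72.1% from 50 tags and 77.6% from 100 tags, and within 5 bases in 74.7%. It was displaced by over 20 bases in 16.0%, 14.3% and, without thinning, 17.3%. A Kolmogorov-Smirnov distance of at least 0.3 gave 9 clusters, against 0 to 2 in the random splits. Total variation gave 883 at 0.3, 0 at 0.7 and 6 from 100 tags. Divergent and convergent shares were 0.327% and 0.537% within 200 bases and 0.966% and 1.54% within 1000 bases. They fell to 0.168% and 0.287% with the majority strand of each cluster and to 0.173% and 0.362% with own clusters of the pooled start sites on separate strands, both chosen after the data were seen.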

Other observations

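All tests here were chosen after the results were seen. Clusters often lay in groups along a strand, with 42241 union clusters in 14777 loci. In loci of 5 clusters with at least 10 CPM in total, the strongest cluster was the one nearest the 5′ end in 10.5% of 712 loci (8.38 to 13.0), against 20% by chance, and in loci of 6 clusters in 8.48% of 625 (6.42 to 10.9), against 16.7%. The strongest was nearest the 3′ end in 14% and 12% of these loci, so both ends held it less often than these chance values. The chance values give every cluster of a locus equal odds, which joining clusters into loci need not do. No conclusion on start site use is drawn. In loci of 3 clusters it was nearest the 5′ end in 37.9% of 467 (33.5 to 42.5), against 33.3%. Of the 13 loci at least 4-fold different, 3 held an eligible cluster, and in the other 10 no single cluster passed the filter on low clusters. The pair of loci on scaffold_6, at 7317560 and 7329239, lay on the same strand. Both were picked as at least 4-fold lower, so their shared direction was fixed by the choice.

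Between the libraries 231 eligible clusters were at least 2-fold different. Counting error of independent tags at the observed depths is argued against, since the highest of the random splits gave 11. With the symbiotic library thinned 257 were found. Removing tags adds counting error, so this number could hardly fall, and no conclusion on depth is drawn from it. The splits do not cover amplified copies, so sampling of fewer molecules than tags may add to the spread. The SD of the log2 ratios was 0.57 at 10 to 20 CPM and 0.29 above 1000 CPM. Such sampling would act on each cluster apart. Where the upstream cluster of an adjacent eligible pair was past 2-fold, 53 of 56 pairs within 200 bases shared its direction. Above 200 and up to 1000 bases 26 of 32 did. For clusters with such a neighbour, this argues against sampling of molecules as the whole cause. A difference between the preparations rather than the conditions stays open and cannot be told apart from an effect of the symbiont, because there was 1 library per condition.

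More of these clusters were lower than higher in the symbiotic library, 73.6% of them. With capped positions, a setting that also changed the eligible set, the share was 36.6%, but the caps cut the deeper symbiotic library harder. By locus it was 52.0% (44.3 to 59.7), and by locus with clusters called at equal depth 62.4% (55.4 to 69.3). Since neighbouring clusters change together, the intervals here come from 10000 draws of blocks on the same strand within 20000 bases. Among clusters, the share was 66.7% (59.4 to 73.6) with the median ratio set to 1. With clusters called and counted at equal depth it was 68.1% (61.5 to 74.3). For eligible clusters this argues against an offset of the median or depth as the whole cause. Scaling in general stays open, since the share was 86.7% with TMM factors. The 36.6% with capped positions cannot decide this, since the caps were unequal between the libraries and also changed the library totals. More tags toward the 3′ end of loci in the aposymbiotic library is argued against as the whole cause. With the median of each of 5 segments of the locus set to that of all segments, 67 were higher and 158 lower, 70.2% (63.1 to 76.8). With the median ratio of each segment set to 1, which corrects the scale as well, 86 were higher and 135 lower, 61.1% (53.1 to 68.5). Scaling, the preparation and the symbiont all stay open.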
